A study of Mus musculus with 4 samples.

How the data were processed

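RNA was sequenced from neural stem and progenitor cells of the mouse dorsal telencephalon at E11.5, grown as free-floating spheres of cells (neurospheres) in medium with basic fibroblast growth factor for 5 days. Per the labels, cells were transduced at plating with lentiviral vectors, either 1 vector carrying a control short hairpin RNA (shControl) at a multiplicity of infection of 30, or 3 vectors carrying hairpins against Phf21b, Zfp7 and Zfp57 at 10 each (the triple knockdown). The genotype label spells a pair of the targets Phf21 and Sfp7, and the names in the treatment label were used. The total dose of virus was 30 in both groups. Per the labels the Zfp7 and Zfp57 hairpins were carried by a different vector backbone from the control hairpin. Vector number and backbone therefore differed between the groups for every gene. Each group had 2 libraries, and all 4 libraries carry the same batch label. Per the labels' protocols, libraries were made from total RNA with an NEBNext Ultra II RNA kit; whether strand was kept, and how transcripts were selected, is not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures or litters. The p-values of the tests of single genes therefore measure only the spread between these libraries, which can be technical.

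The authors deposited 1 table of estimated counts per gene, not normalized, for 34866 Ensembl gene identifiers. Per the submitters' processing notes the counts came from Salmon with the mouse builds GRCm38 and mm10; the Salmon version, the annotation release and the way transcripts were summed to genes are not given in the sources used here. Between 23.1% and 25.1% of the values in a library were not whole numbers, and these estimated counts, as deposited, were rounded to whole numbers before testing. Through rounding the library totals fell by 195, fell by 140, fell by 152 and fell by 135 counts. Total counts were 20779211 and 14694387 in shControl replicates 1 and 2, and 17901386 and 15170491 in triple knockdown replicates 1 and 2. All 4 columns belong to the series' samples.

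Identifiers were matched without their version to GENCODE M21 (GRCm38), which gave a symbol and position for 34582 of them, 32574 with the same version. The other 284 stayed in the tests without a symbol. A total of 12597 identifiers were at 0 in every library. For each gene, the percentage of its transcripts' 31-mers also found in another gene was computed from the M21 transcripts, and genes with a high share are named as uncertain, because a transcript quantifier divides such reads by a model. Exonic overlap with other genes was computed from the same annotation.

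Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors (1.04, 0.907, 1.05 and 1.01 for the libraries in the order above), filterByExpr with a minimum count of 10, which kept 14050 genes, a robust quasi-likelihood fit and a two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are given in CPM, the count relative to the library total scaled by its TMM factor, as mean ± SD of 2 libraries. Fold changes are triple knockdown over shControl, and percentages of the control level carry 95% intervals from the SE. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, so no such test was used.

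Before the data were examined, 39 gene lists were fixed: neuronal, progenitor, glial and patterning genes, markers of other cell types, chromatin, signalling, stress and cell cycle genes. The 37 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 37 lists. The same test with a correlation estimated from each list, and the rotation test fry, for a shared direction and for changes in either direction, were also run. With the preset correlation, camera compares a list's members with the other tested genes and takes its degrees of freedom from the number of genes. Those p-values therefore mainly reflect the spread between genes, not the spread between libraries. With an estimated correlation, camera takes its degrees of freedom from the residuals, here 2, so few lists can pass whatever their correlation. The interferon list had an estimated correlation of 0.0029, below the preset value, and still an adjusted p of 0.41 in that camera test. Counts of list members past the threshold are given over all tested genes and adjusted over the list alone. The genes named were also fixed by rule: the 3 targeted genes; the 12 genes with the most positive and the 12 with the most negative fold change among those past the threshold with a mean of at least 1 CPM, separated libraries and no clone name; up to 4 members of each list past the threshold by smallest p, or else up to 3 by highest CPM as values; and Nr2f1, Nr2f2, Hmga2 and Lin28b. Genes named outside this rule are marked as chosen after their values were seen.

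Replicates were compared before averaging. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.979 between the shControl libraries and 0.984 between the triple knockdown libraries, and 0.975 to 0.977 across groups. A chi-square statistic per degree of freedom of 17.1 and 6.94 in the respective groups exceeded sampling noise, so no pair was a repeated library. Across groups it was 20.7 and 11 for shControl replicate 1, and 29.1 and 19.4 for shControl replicate 2, against triple knockdown replicates 1 and 2. By this measure shControl replicate 1 was nearer to triple knockdown replicate 2 than to the other control. The common dispersion was 0.0132.

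The test was tried on simulated counts for this comparison, drawn from negative binomial distributions with the real mean levels, library sizes and trended dispersions, and 13817 simulated genes were tested. It recovered 31.3% of 67 genes changed 1.5-fold, 67.2% of 64 changed 2-fold and 95.3% of 64 changed 4-fold, with 10 unchanged genes among 144 calls. A list of 20 genes raised 1.5-fold had a camera adjusted p of 1.2e-14 and a list of 20 unchanged genes 0.61. Genes were drawn independently of each other, so false calls among lists with correlated members were not measured. The simulated counts also held no gene-specific dispersion and no variation shared across a library. Recovery and false calls in the real data may therefore be worse than these figures. The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters and thresholds, the replicate number as a block, each library left out, and an estimated correlation. DESeq2 was run on the 22122 genes with at least 1 count, without its own filtering by mean count. Its adjustment therefore covered more genes than the 14050 of the main fit. After the data were examined, fits without mitochondrially encoded genes and without genes sharing over 50% of their 31-mers were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation, further tests and figures.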

Results

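The series measured gene expression by RNA sequencing in neural stem and progenitor cells cultured from the mouse dorsal telencephalon, the part of the forebrain that forms the cerebral cortex. Cells taken at E11.5 were transduced and grown as neurospheres for 5 days. The 2 shControl libraries held 20779211 and 14694387 estimated counts, and the 2 triple knockdown libraries, which received hairpins against Phf21b, Zfp7 and Zfp57 together, held 17901386 and 15170491. The series title places the comparison in a search for transcriptional regulators that time the production of neuron subtypes. The question addressed was which genes differ when the 3 factors are targeted together.

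Transcript levels of the 3 targeted genes were below control by 1.23-fold to 1.32-fold, and none of the differences passed the threshold over all tested genes. Zfp57, a KRAB zinc-finger protein that maintains genomic imprints (ENSMUSG00000036036.15, chromosome 17, 37001163 to 37010635 in GRCm38), measured 13.2 ± 1.97 CPM in shControl and 10.0 ± 0.988 CPM in the triple knockdown (SD, n = 2 each). Its log2 fold change was -0.40 (SE 0.18; edgeR adjusted p = 0.341), which is 75.6% of control with a 95% interval of 58.9% to 97.1%. Phf21b, a PHD-finger protein (ENSMUSG00000016624.15, chromosome 15, 84785381 to 84856049), measured 7.30 ± 0.0823 CPM against 5.97 ± 0.678 CPM, or 81.6% of control (60.8% to 109%; log2 fold change -0.29, SE 0.22, edgeR adjusted p = 0.644). Zfp7, a zinc-finger gene (ENSMUSG00000033669.8, chromosome 15, 76879259 to 76892395), measured 1.963 ± 0.411 CPM against 1.48 ± 0.704 CPM, or 77.6% of control (44.8% to 134%; log2 fold change -0.37, SE 0.40, edgeR adjusted p = 0.80). Both knockdown libraries lay below both control libraries for Zfp57 and Phf21b but not for Zfp7. Adjusted over the list alone, the 3 p-values were 0.093, 0.27 and 0.37 for Zfp57, Phf21b and Zfp7, so 0 of 3 passed. The Zfp7 counts were low, at 36.1, 30.2, 36.8 and 15 estimated reads, and 20.5% of its 31-mers occur in another gene. Its log2 fold change was 0.03 without triple knockdown replicate 2 and -0.98 without triple knockdown replicate 1. That of Zfp57 was -0.23 without shControl replicate 1 and -0.53 without shControl replicate 2. For Phf21b it was -0.18 without triple knockdown replicate 1 and -0.41 without triple knockdown replicate 2. Protein levels were not analysed here.

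**Figure D1:**
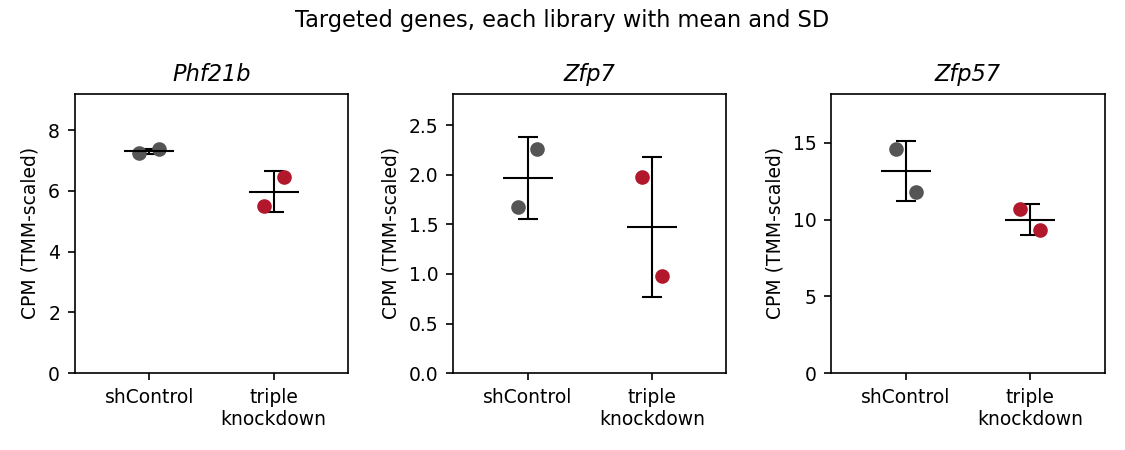
TMM-scaled CPM (vertical axes, starting at 0) of the 3 targeted genes in each of the 2 shControl libraries (grey points) and 2 triple knockdown libraries (red points), with the mean as a horizontal line and the SD as error bars. The Zfp57 means are 13.2 and 10.0 CPM, the Phf21b means 7.30 and 5.97 CPM, and the Zfp7 values of the groups overlap.

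Genes of the interferon response rose in the triple knockdown, and genes of neurons were among those that fell. Among genes with a mean of at least 1 CPM and no clone or pseudogene name, the highest fold changes belonged to Usp18, a protease that removes Isg15 from proteins (log2 fold change 3.90, SE 0.57), Rtp4, of which 13.9% of exonic bases overlap Gm45338 (3.16, SE 0.21), Ifi27 (2.99, SE 0.20), Mx2, annotated as a polymorphic pseudogene (2.73, SE 0.50) and Isg15, a ubiquitin-like modifier (2.54, SE 0.35). Genes outside the interferon list that rose were Tmem170 (2.51, SE 0.18), the homeobox gene Dbx2 (2.26, SE 0.46) and Neu1, a lysosomal sialidase (2.17, SE 0.18). Among genes that fell were Neurod6, a transcription factor of cortical projection neurons (-1.12, SE 0.16), Nit2, an omega-amidase (-1.38, SE 0.16), Shisa6, an AMPA receptor auxiliary subunit (-2.28, SE 0.54), and the receptor tyrosine kinase Axl (-1.39, SE 0.34). In total 192 of 14050 genes had an adjusted p under 0.05 in edgeR's quasi-likelihood test, 76 higher and 116 lower, and 1685 had an unadjusted p under 0.05. The knockdown libraries lay entirely above or below the control libraries for 5796 genes (41.3%), against 33.3% by chance. Median log2 fold changes were 1.29 for the higher and -0.72 for the lower genes, and 45 higher and 23 lower genes changed at least 2-fold. The higher set included 24 annotated pseudogenes, Mx2 among them, and the lower set 4. Scaling by library size alone gave 77 higher and 28 lower genes. DESeq2, run over 22122 genes without its own filtering by mean count, gave 23 and 32. The counts without 1 library were 112 and 184 (shControl replicate 1), 280 and 334 (shControl replicate 2), 27 and 17 (triple knockdown replicate 1) and 36 and 27 (triple knockdown replicate 2).

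The remaining genes of the ranked sets were spread over several functions. Bst2, which tethers budding virus particles, rose 5.58-fold, from 2.40 ± 0.094 to 13.5 ± 0.0378 CPM (edgeR adjusted p = 2.13e-14). Gbp3 and Irgm1, which encode interferon-inducible GTPases, had log2 fold changes of 2.44 and 1.63 (adjusted p = 0.00117 and 0.00488), and Trim30b of 2.07 (adjusted p = 0.0394). Without shControl replicate 1 and without shControl replicate 2 the log2 fold changes were 1.84 and 3.11 for Gbp3, and 1.28 and 3.12 for Trim30b. Tmem170 rose from 5.86 ± 0.738 to 33.0 ± 1.43 CPM and Neu1 from 6.81 ± 0.362 to 30.4 ± 5.45 CPM (edgeR adjusted p = 1.13e-19 and 2.05e-16). Usp18 had only 4 and 2 counts in the control libraries against 42 and 48, a ratio of 15.4 with a 95% counting interval of 6.79 to 43.0. On the lower side, Nit2 went from 35.3 ± 3.57 to 13.6 ± 1.34 CPM (adjusted p = 7.99e-10) and the collagen gene Col9a3 from 10.8 ± 0.888 to 4.62 ± 0.653 CPM (adjusted p = 4.86e-05). Tle2, a Groucho-type corepressor, Fabp4, a fatty acid-binding protein, Kifc2, a kinesin, Rnf152, Tmem145 and Diras1 fell with log2 fold changes of -1.42, -1.64, -1.30, -1.24, -1.16 and -1.09. Pcdha4 (-1.51) is uncertain, since 92.2% of its 31-mers are shared within the protocadherin alpha cluster. Usp18, Rtp4, Ifi27, Isg15, Tmem170, Bst2, Neu1, Nit2 and Neurod6 stayed past the threshold in 13 of 13 alternative fits. Tmem145 stayed past it in 2, Shisa6, Fabp4 and Diras1 in 8, Trim30b, Axl and Kifc2 in 9, and Gbp3, Tle2 and Rnf152 in 10, and Pcdha4 in 10 of 12. Mx2, Dbx2 and Irgm1 stayed past it in 11 and Col9a3 in 12.

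**Figure D2:**
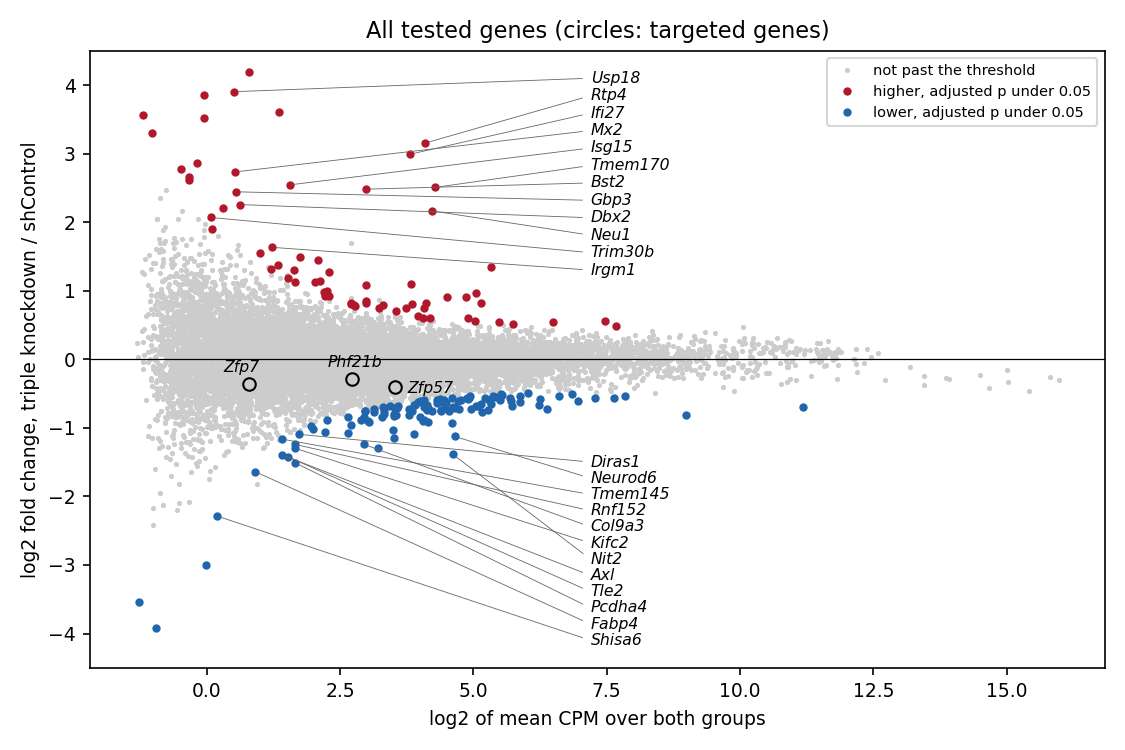
Log2 fold change of triple knockdown over shControl (vertical axis) against log2 of the mean CPM over both groups (horizontal axis) for the tested genes; red and blue points are the higher and lower genes past the threshold, and circles mark the 3 targeted genes. Ifi27, Rtp4, Tmem170 and Neu1 stand apart from other genes at their level, and 8 pseudogenes with 0 counts in a whole group are not drawn.

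Interferon-stimulated genes rose as a group. Of 16 tested members 7 rose, 0 fell and 9 did not pass the test, and 11 rose when adjusted over the list alone. Ifi27 rose from 3.14 ± 0.0882 to 25.1 ± 0.967 CPM, Rtp4 from 3.29 ± 1.78 to 31.1 ± 3.35 CPM and Isg15 from 0.854 ± 0.0397 to 5.02 ± 1.11 CPM (edgeR adjusted p = 3.44e-21, 2.05e-16 and 1.76e-07). The Rtp4 control libraries measured 4.552 and 2.028 CPM, and its log2 fold change was 3.93 without shControl replicate 1 and 2.78 without shControl replicate 2. The list's median log2 fold change was 1.71 (camera adjusted p = 9.34e-18; adjusted p = 0.41 with an estimated correlation; fry adjusted p = 0.036). The fixed list held 24 genes, of which these 16 were tested. The median was 1.40 without the filter on low counts and 1.45 with a filter of at least 1 CPM in 2 libraries. Both knockdown libraries exceeded both controls for 13 of the 16 genes. Markers of microglia and other myeloid cells, which respond to interferon, had a median log2 fold change of -0.07 and a mean of 0.05 over 10 tested genes (camera adjusted p = 0.98, direction higher), with 0 past the threshold and 1, Ptprc, when adjusted over the list alone. Lyz2 measured 15.4 ± 1.65 against 11.2 ± 2.14 CPM, Ptprc 7.74 ± 3.39 against 11.6 ± 1.47 CPM and Tyrobp 5.82 ± 0.157 against 5.40 ± 1.10 CPM. Genes of the NF-kB response had a median of 0.19 over 7 tested genes (camera adjusted p = 0.266), with 0 past the threshold and 1 when adjusted over the list alone.

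Neuronal genes were lower as a group. Of the 20 pan-neuronal genes, 3 fell and 17 did not pass, and 5 fell when adjusted over the list alone. Tubb3, the neuronal beta-tubulin, fell from 103 ± 20.9 to 62.9 ± 1.92 CPM (log2 fold change -0.72, SE 0.14, edgeR adjusted p = 0.000445). Nsg2, a neuronal endosomal protein, fell from 186 ± 25.9 to 126 ± 2.69 CPM (adjusted p = 0.0144), and Celf4, an RNA-binding protein, from 25.0 ± 1.08 to 16.7 ± 1.16 CPM (adjusted p = 0.0437). The list's median log2 fold change was -0.26 (camera adjusted p = 0.00169; adjusted p = 0.66 with an estimated correlation). Synaptic transmission genes had a median of -0.38 over 20 members (camera adjusted p = 0.00442; adjusted p = 0.66 with an estimated correlation). Of these 0 passed the threshold over all genes or adjusted over the list alone. Gria2 measured 102 ± 9.13 against 83.5 ± 7.45 CPM and Syp 34.2 ± 2.00 against 26.6 ± 1.98 CPM. In the list of Cajal-Retzius and preplate genes, Calb2, which encodes calretinin, fell from 38.4 ± 5.89 to 23.4 ± 1.98 CPM (adjusted p = 0.00202). The list's median was -0.31 over 11 members (camera adjusted p = 0.717), with 1 higher and 2 lower when adjusted over the list alone. Without shControl replicate 1 the pan-neuronal and synaptic lists had camera adjusted p-values of 0.061 and 0.088. Without triple knockdown replicate 1 the pan-neuronal list had 0.056. The synaptic median was -0.25 without triple knockdown replicate 2. The calls of Tubb3, Nsg2 and Celf4 were lost with scaling by library size alone and without either triple knockdown library. Nsg2 was also lost without shControl replicate 1, and Celf4 with DESeq2 and a replicate block.

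Genes tied to the birth order of cortical neurons did not pass as lists. Deep-layer neuron genes, which mark early-born projection neurons, had a median log2 fold change of -0.18 over 15 members (camera adjusted p = 0.125), and upper-layer genes, which mark later-born neurons, one of -0.17 over 15 members (camera adjusted p = 0.242). In each list 0 members passed the threshold over all genes or adjusted over the list alone. The directional fry adjusted p-values were 0.089 for the deep-layer and 0.44 for the upper-layer list, with 12 and 9 members below 0. Among deep-layer genes, Etv1 measured 42.6 ± 2.59 against 39.3 ± 3.57 CPM and Tle4 16.1 ± 0.438 against 16.7 ± 2.03 CPM. Among upper-layer genes, Lmo4 measured 62.6 ± 3.43 against 66.2 ± 1.24 CPM and Pou3f3 37.0 ± 2.39 against 32.5 ± 0.536 CPM. Without 1 library or under other settings the medians ranged from -0.25 to -0.09 and from -0.18 to -0.07.

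Progenitor genes of the late, glia-competent stage were lower as a group, and those of the early stage did not pass as a list; the difference between the lists was not tested. Among 18 late-stage genes 2 fell, 16 did not pass, and 5 fell when adjusted over the list alone. Hopx, a marker of radial glia, fell from 115 ± 3.06 to 79.2 ± 3.12 CPM (log2 fold change -0.53, SE 0.13, edgeR adjusted p = 0.0163), and Tnc, which encodes the matrix protein tenascin C, from 13.4 ± 2.49 to 8.28 ± 0.549 CPM (log2 fold change -0.69, SE 0.19, adjusted p = 0.0418). For Hopx, 27.2% of the exonic bases overlap an antisense gene. The late list's median was -0.28 (camera adjusted p = 0.00922; adjusted p = 0.66 with an estimated correlation). Among 12 early-stage genes 1 fell, 0 rose and 11 did not pass, while 2 rose and 2 fell when adjusted over the list alone. The median was -0.05 (camera adjusted p = 0.742), and 0.03 with scaling by library size alone. The gene that fell was Nr2f1, a nuclear receptor that patterns the cortex, from 48.9 ± 1.03 to 33.8 ± 0.637 CPM (log2 fold change -0.53, adjusted p = 0.0288). Nr2f2 (-0.63, adjusted p = 0.0945), Hmga2 (0.55, adjusted p = 0.15) and Lin28b (-0.39, adjusted p = 0.725) did not pass. Over the alternatives their log2 fold changes ranged from -0.92 to -0.38, from 0.31 to 0.79 and from -0.73 to -0.02. The late list's adjusted p was 0.097 without shControl replicate 2 and 0.053 without triple knockdown replicate 2. The late median was -0.18 without shControl replicate 1, and the early median ranged from -0.15 to 0.03 over the alternatives. The calls of Hopx, Tnc and Nr2f1 were lost with scaling by library size alone and without either triple knockdown library. Nr2f1 was also lost with DESeq2 and a replicate block. Tnc was also lost with DESeq2, with limma-voom, without shControl replicate 2 and without genes sharing over 50% of their 31-mers, and held in 6 of 13 alternatives.

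Dorsal telencephalic patterning genes were lower as a group, with a median log2 fold change of -0.27 over 12 members (camera adjusted p = 0.0242; adjusted p = 0.66 with an estimated correlation), with 0 past the threshold and 3 lower when adjusted over the list alone. Lhx2 measured 40.0 ± 3.58 against 33.1 ± 1.04 CPM and Pax6 28.0 ± 0.0955 against 23.7 ± 0.544 CPM. Proneural and intermediate progenitor genes had a median of -0.22 over 15 members (camera adjusted p = 0.0703), with Neurod6 lower, from 34.3 ± 7.02 to 15.9 ± 2.16 CPM, and 3 lower when adjusted over the list alone. Radial glia genes had a median of -0.09 over 18 members (camera adjusted p = 0.414) with 0 past the threshold either way. The abundant radial glia gene Fabp7 measured 25000 ± 3620 against 21430 ± 1880 CPM. In the astrocyte list, Sparcl1 fell from 33.1 ± 2.45 to 20.1 ± 0.557 CPM (adjusted p = 0.00268), 1 of 10 members and 2 when adjusted over the list alone (list median -0.15, camera adjusted p = 0.211). Globin and other red blood cell genes were higher as a group, with a median of 0.56 over 6 members (camera adjusted p = 0.00547; adjusted p = 0.66 with an estimated correlation). Of these Hbb-y, an embryonic beta-globin, rose by a log2 fold change of 0.63 (SE 0.17, adjusted p = 0.0399) and 3 rose when adjusted over the list alone. The dorsal list did not pass without either shControl library or without triple knockdown replicate 1 (adjusted p = 0.12, 0.097 and 0.20). The red blood cell list did not without either shControl library or without triple knockdown replicate 2 (0.053, 0.25 and 0.11).

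Stress, ribosomal and mitochondrial genes also passed as lists in camera with the preset correlation of 0.01. Their estimated correlations, at 0.51, 0.35 and 0.87, lay far above that preset. Among 19 genes of the integrated stress and unfolded protein responses 2 rose and 17 did not pass, with the same number adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme, rose from 10.4 ± 1.56 to 18.3 ± 1.68 CPM and Asns, asparagine synthetase, rose by a log2 fold change of 0.60 (edgeR adjusted p = 0.00392 and 0.042). The list's median log2 fold change was 0.28 (camera adjusted p = 0.00442; adjusted p = 0.72 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.12 over 79 members with 0 past the threshold either over all genes or adjusted over the list alone (camera adjusted p = 0.00169; adjusted p = 0.74 with an estimated correlation). Rps24 measured 5512 ± 916 against 5667 ± 13.1 CPM. Genes encoded by mitochondrial DNA took 30.3% and 33.9% of the counts in the shControl libraries and 26.6% and 28.5% in the triple knockdown libraries. Their median was -0.31 over 13 members (camera adjusted p = 0.00169; adjusted p = 0.72 with an estimated correlation). Of these mt-Nd3 fell from 2873 ± 856 to 1774 ± 36.3 CPM (adjusted p = 0.0123), 1 of 13 also when adjusted over the list alone. However, 98.1% of the 31-mers of mt-Nd3 occur in another gene. Without triple knockdown replicate 1 the stress, ribosomal and mitochondrial lists had adjusted p-values of 0.068, 0.063 and 0.059. Without shControl replicate 2 the stress list had 0.57 and a median of 0.14, and the mitochondrial list had 0.16 and a median of -0.14. The ribosomal median was 0.02 without shControl replicate 1 (adjusted p = 0.46), 0.23 without shControl replicate 2 and 0.21 with scaling by library size alone. The mitochondrial list had 0.054 when genes sharing over 50% of their 31-mers were left out.

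Imprinted genes, which Zfp57 is known to regulate, went in both directions. Of 28 tested members Mest rose from 169 ± 19.9 to 238 ± 1.28 CPM and Peg3 fell from 27.3 ± 4.03 to 16.7 ± 2.53 CPM (log2 fold changes 0.49 and -0.70; edgeR adjusted p = 0.0475 and 0.00739). The other 26 did not pass, and 1 rose and 3 fell when adjusted over the list alone. The list's median was 0.00 and its mean -0.08 (camera adjusted p = 0.717, direction lower; fry adjusted p = 0.41 for a shared direction and 0.017 for changes in either direction). For Mest, 23.1% of the exonic bases overlap the antisense gene Copg2. Cell cycle genes had 0 of 26 S-phase members and 0 of 26 G2 and mitosis members past the threshold over all genes or adjusted over the list alone, with medians of 0.05 and -0.01 (camera adjusted p = 0.717 and 0.98, both with direction higher). Pcna measured 454 ± 28.1 against 500 ± 36.2 CPM and Cdk1 199 ± 12.8 against 207 ± 6.92 CPM. Among FGF and ERK target genes Dusp6, a phosphatase that dampens ERK, rose from 12.6 ± 0.175 to 22.2 ± 0.26 CPM (adjusted p = 0.00135), also the 1 member past the threshold when adjusted over the list alone. The list's median was 0.17 over 13 members (camera adjusted p = 0.242). Among p53 target genes Trp53inp1 fell, with a log2 fold change of -0.71 (SE 0.16, adjusted p = 0.00521). In that list 3 members fell when adjusted over the list alone, with a median of -0.09 over 20 members (camera adjusted p = 0.98). Of the 37 lists, 4 were higher, 5 were lower and the other 28 did not pass, and 0 passed with an estimated correlation. That test rested on 2 residual degrees of freedom, so by itself it cannot show that correlation between genes undid the calls. The estimated correlations were 0.0029 (interferon), -0.12 (red blood cell), -0.028 (late progenitor), -0.076 (dorsal telencephalic), 0.044 (pan-neuronal), 0.04 (synaptic), 0.51 (stress), 0.35 (ribosomal) and 0.87 (mitochondrial). Those of the stress, ribosomal and mitochondrial lists lay far above the preset 0.01. For these lists the camera p-values with the preset are therefore likely too small. With the directional fry test, which does not compare a list with other genes, 1 of the 9 lists, interferon, had an adjusted p under 0.05. The others had fry adjusted p-values of 0.17 (pan-neuronal), 0.15 (synaptic), 0.089 (late progenitor), 0.089 (red blood cell), 0.13 (dorsal telencephalic), 0.44 (stress), 0.44 (ribosomal) and 0.43 (mitochondrial). Among lists that camera did not call, deep-layer neuron genes had 0.089 in this fry test, the same as the late progenitor list, and Wnt target genes 0.056. In the fry test for changes in either direction 9 of the 37 lists had an adjusted p under 0.05. These were dorsal telencephalic (0.013), pan-neuronal (0.034), FGF and ERK target (0.019) and, at 0.017 each, interferon, ribosomal, late progenitor, astrocyte, imprinted and immediate-early genes. The calls of Mest, Peg3, Dusp6, Trp53inp1, Calb2, Sparcl1, Hbb-y, Mthfd2, Asns and mt-Nd3 were all lost without triple knockdown replicate 1. Those of Mest, Dusp6, Sparcl1, Hbb-y, Asns and mt-Nd3 were also lost without triple knockdown replicate 2, and those of Mest, Asns and mt-Nd3 without shControl replicate 2. Scaling by library size alone ended those of Mest, Peg3, Trp53inp1, Calb2, Sparcl1, Hbb-y and Asns. DESeq2 ended those of Peg3, Trp53inp1, Hbb-y, Mthfd2, Asns and mt-Nd3, and a replicate block those of Mest, Hbb-y and mt-Nd3. Mest was also lost without the filter on low counts and without mitochondrially encoded genes, and held in 6 of 13 alternatives; mt-Nd3 held in 6 of 11.

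**Figure D3:**
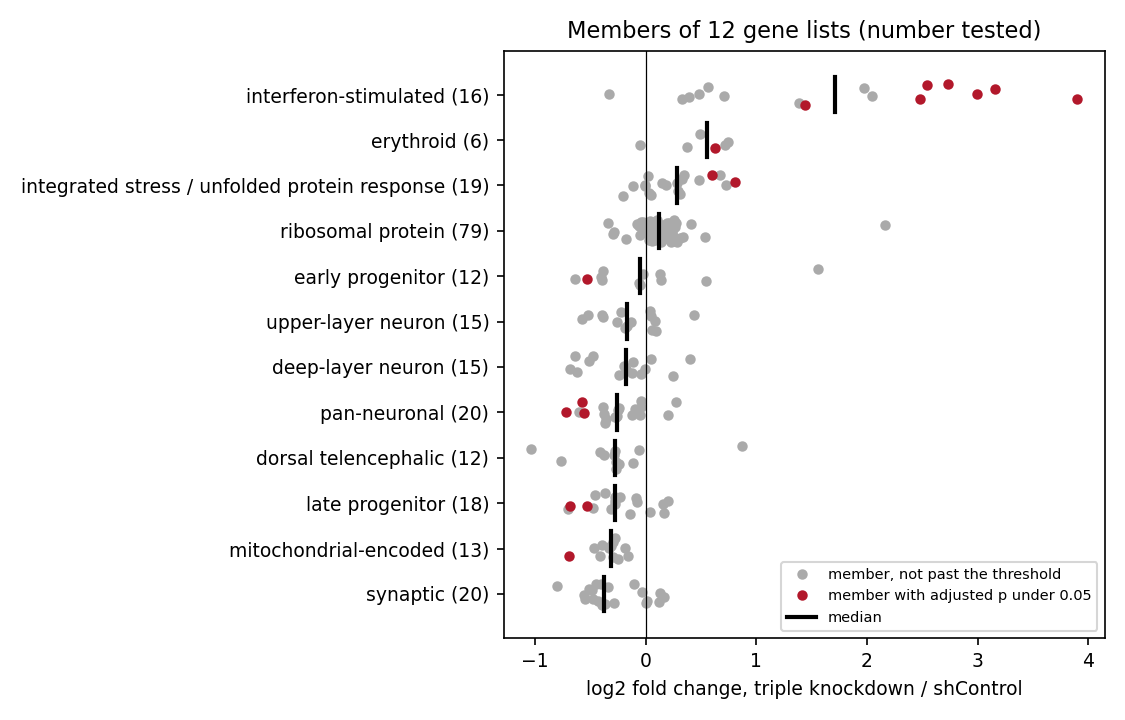
Log2 fold change of triple knockdown over shControl (horizontal axis) for each tested member of 12 gene lists (with the number tested); red points passed an adjusted p of 0.05, grey points did not, and black bars are medians. The interferon list lies at a median of 1.71, while the medians of the other lists shown lie between -0.38 and 0.56.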

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

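The fits without mitochondrially encoded genes and without genes sharing over 50% of their 31-mers were chosen after seeing the data; the others were planned. With 2 libraries per group, the counts of genes past the threshold moved most when a library was left out: 27 to 280 higher genes (76 with all libraries) and 17 to 334 lower genes (116). Of the original genes, 24 and 11 were kept without triple knockdown replicate 1. The lone library is then assumed to vary like the other group. DESeq2, over 22122 genes and without its own filtering by mean count, called 23 higher and 32 lower genes, all among the original ones. Over as many genes, edgeR without the filter on low counts called 84 and 128. An adjusted p under 0.01 left 37 and 56, and scaling by library size alone left 28 lower genes, 26 of them shared. Lists called higher numbered 2 to 4 and lists called lower 2 to 5 without 1 library, and 0 and 0 with a correlation estimated per list, where the late progenitor median of -0.28 had an adjusted p of 0.66. Without 1 library that median ranged from -0.29 to -0.18. The test with an estimated correlation rested on 2 residual degrees of freedom, so few lists could pass it. The early progenitor median was 0.026 with library size alone, against -0.05, while the median of all tested genes moved from -0.0085 to 0.072, a shift of similar size. Values of genes that never passed changed sign without triple knockdown replicate 2: over the fits without 1 library Zfp7 ranged from -0.98 to 0.028, Tle4 from -0.078 to 0.17 and Tyrobp from -0.33 to 0.089. Of 40 named genes past the threshold, 39 stayed so with DESeq2-type size factors, 37 with limma-voom, 25 with library size alone, 17 with DESeq2, and 33, 33, 11 and 17 without shControl replicate 1, shControl replicate 2, triple knockdown replicate 1 and triple knockdown replicate 2; 0 changed sign. The replicate numbers share no stated origin, and same-numbered libraries' deviations had a correlation of -0.032 across genes; a fit with the replicate block called 75 higher and 97 lower genes, 70 and 95 of them shared. Depth limits the low genes, since 3 counts correspond to 0.139 to 0.225 CPM.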

Other observations

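The genes in the paragraphs on single genes outside the lists, zinc-finger genes and pseudogenes were chosen after their values were seen, and of the tests below only those on gene length and on genomic clusters were set before their result was seen. For the clusters a window of 5 Mb was first planned, but the written prediction named only 1 Mb.

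Single genes outside the fixed lists also rose. Ifitm3, an interferon-induced membrane protein that blocks virus entry, rose by a log2 fold change of 1.34 (edgeR adjusted p = 7.22e-11). Eif4ebp1, a translation repressor, and Cth, an enzyme of cysteine synthesis, rose by 0.97 and 0.74 (adjusted p = 4.77e-06 and 0.0117). Pf4, Arhgdib and Spp1, which blood and myeloid cells express, rose by 0.80, 0.98 and 0.55 (adjusted p = 0.0121, 0.021 and 0.0155).

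In a cluster of zinc-finger genes on chromosome 2, between 175129493 and 178078476 in GRCm38, single genes fell in the triple knockdown. Of its 30 tested protein-coding genes 26 had a log2 fold change below 0, the median was -0.36, and 6 passed the threshold: Zfp968, Zfp965, Zfp971, Gm14435, Gm14325 and Gm14326. The 30 genes shared a median of 91.6% of their 31-mers with another gene (33.6% to 100%), so the levels of many are uncertain and their directions are not independent, and the cluster was not tested as a group.

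Among explanations for the rise of interferon-stimulated genes, more myeloid cells would have raised their markers alongside, but the median log2 fold change of the 10 tested markers was -0.07 (bootstrap SE 0.19) against 1.71, although Pf4, Arhgdib and Spp1 rose and Ptprc, 1 of the 10, rose 1.54-fold when adjusted over the list alone. The Ptprc control libraries measured 5.341 and 10.14 CPM, and its log2 fold change of 0.625 ranged from 0.20 to 1.13 over the alternatives. Of the 10 tested markers, 6 reached 1 CPM in the controls, and 0 of the 13 markers are on another list. Of the 16 tested genes, 13 had both knockdown libraries above both controls and 1 had both below. The filter needed enough counts in at least 2 libraries. A gene near 0 in the controls was thus tested only if both knockdown libraries expressed it. The count therefore cannot exclude a single aberrant knockdown library for the list. Ifi27 and Bst2, at 3.205 and 3.08 and at 2.462 and 2.329 CPM in the controls, did not depend on this. Both knockdown libraries were higher there, at 25.8 and 24.43 and at 13.43 and 13.49 CPM. Sensing of the mixture of 3 vectors cannot be told apart from lower levels of the 3 factors, whose transcripts stood at 75.6% to 81.6% of control with none past the threshold, because 0 libraries received 3 vectors without the targeting hairpins, and per the labels the Zfp7 and Zfp57 hairpins were carried by a different vector backbone from the control hairpin. A response within the existing cells, to the vectors or to the targeting, therefore stays open as a hypothesis.

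The lower neuronal genes were weighed against 2 explanations. A bias by gene length, GC content or expression is argued against, since 0 of 10000 random lists matched on these had a median as low as the -0.31 of the 40 pan-neuronal and synaptic genes, and the central 95% of matched medians ran from -0.13 to 0.04. Fewer neurons beside unchanged progenitors would place the radial glia median above 0, but it was -0.09 (bootstrap SE 0.05), too close to 0 to exclude this. The late progenitor and dorsal telencephalic medians were -0.28 and -0.27, but their camera calls were lost in some alternatives. In the directional fry test these 2 lists had adjusted p-values of 0.089 and 0.13. Whether progenitors were unchanged therefore stays undecided. Whether neurons were fewer or expressed less of these genes may be asked of the cells directly. An effect of lowering the 3 factors, which the transcript levels did not establish, remains an untested biological explanation. Vector number and backbone also differed between the groups, and their effects on these genes cannot be told apart from those of the targeting.

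Pseudogenes made up 28 of the 192 genes past the threshold (14.6%, against 3.87% of the other tested genes; Fisher's exact test, two-sided, p = 3e-09), and 26 of 190 (13.7% against 3.83%, exact p = 3.4e-08) without the interferon-stimulated polymorphic pseudogenes Mx2 and Oas1b, of which 7.96% and 6.70% of 31-mers are shared. In 8 both libraries of a group had 0 counts, and in 7 of these the controls were at 0, with knockdown levels at least 8.59-fold to 23.4-fold above the floor of 3 counts over the group. Reads shared with near-identical genes are a candidate explanation, since the 28 shared a median of 94.7% of their 31-mers against 47.3% for other tested pseudogenes (95.3% against 48.0% without the polymorphic ones), though 3 of the 8, Gm13508, Rps16-ps3 and Gm12901, shared 8.19%, 13.9% and 16.9%. Embryos of different genetic background cannot be excluded: 40 of 192 genes past the threshold lay within 1 Mb of another, against a median of 46 in 10000 random draws (one-sided permutation p = 0.79), and 123 within 5 Mb, against 113 (permutation p = 0.11), but a difference spread over all chromosomes would leave no clusters. Lower levels of the 3 factors as a biological cause were not tested for these genes, and cannot be told apart from effects of the differing vectors.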
